A study of Homo sapiens with 8 samples.

How the data were processed

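RNA from 8 samples of JVM13 was measured on an Affymetrix human expression array. JVM13 is an established human B-cell line derived from a prolymphocytic leukaemia. Cells carried a doxycycline-inducible vector with wild-type cyclin D1 (n = 3), with the stable T286A form of cyclin D1 (n = 3) or with no insert (empty vector, n = 2), and all were given 0.1 µg/mL doxycycline, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a group were separate cultures, so p-values of single genes measure the spread between these samples, which may be technical. They also do not say how many independently made populations stand behind each construct, how long induction lasted, or when the arrays were scanned.

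The deposited values are log2 expression values made by robust multi-array averaging (RMA) in R 3.5.0, per the submitters' processing notes. RMA subtracts background, gives all arrays the same distribution of probe intensities and summarises the probes of a probe set. Its equal distributions remove any change in the total amount of mRNA per cell, so each change below is relative to the other genes. Background that remains in dim probe sets makes fold changes too small. The values carry no detection call, scanner files were not used here, and the number of arrays limits the precision. The table held 48864 probe sets, of which 10 were human control probe sets and were left out. Among the others, 45220 were annotated to 1 gene, 1325 to several genes and 2309 to none. The annotation is that of the array platform. Of the named probe sets, 45144 had a gene identifier found in the reference gene table, and 0 symbols needed an update. No values were missing, and 0 pairs of arrays held identical values. The sorted values of any 2 arrays differed by at most 0.17 (log2).

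For each of 18231 genes, the probe set with the highest mean over all arrays was used; 11820 genes had more than 1 probe set. All 8 arrays were fitted together with a mean per group in limma 3.58.1 (R 4.3.3; lmFit and eBayes with default settings), so that the groups shared 1 estimate of the spread with 5 residual degrees of freedom and 3.27 prior ones. No intensity filter was used. Comparisons were the mean of both constructs against empty vector, each construct against empty vector, and T286A against wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and every adjusted p of a gene comes from this two-sided test. Values are log2 differences ± SE unless said otherwise.

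Before the data were examined, 28 gene lists with 607 entries were fixed, of which 564 were measured. Each list was tested with limma's camera (preset correlation between genes of 0.01, two-sided, Benjamini-Hochberg over the lists), and again with a correlation estimated from the data. Camera compares the genes of a list with all other genes. With the preset correlation its p-value rests mainly on the spread between genes, not between arrays. With an estimated correlation it also takes its degrees of freedom from the arrays, which by itself makes p-values larger. Members were counted with p adjusted over all genes and adjusted over the list alone. A rule fixed at the same time chose the genes named here. CCND1 came first. Then, per comparison, it took the 12 largest rises and the 12 largest falls among called genes whose arrays did not overlap between the 2 sides and whose mean in the higher side was at or above the median of all genes (5.94, log2). From each list it took up to 4 called members with the largest change, or, where none was called, up to 2 with the smallest p. For calls shared by both constructs it took up to 10 genes per direction. Genes on the Y chromosome, XIST and antigen receptor segments were not named. Paralogs with near-identical probes, such as AKR1C1, CYP4F2, APOBEC3B, HSPA1B, HLA class II and histone genes, are uncertain, because a probe set can read a relative. Of 195 called results for genes in the comparisons that the rule chose them for, CCND1 apart, 145 belonged to genes with more than 1 probe set. Another probe set was called in the same direction in 55 of these, and in 0 was a probe set called in the opposite direction.

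The comparisons of each construct with empty vector share the same 2 control arrays. Their overlap was set beside 100 simulations of unchanged groups against shared controls. The fit was tested on simulated data with 200 changed genes among 18231 in 5 simulations. At a planted log2 change of 0.5 it recovered 68.4% of changed genes for wild type against empty vector, 55.8% for T286A against empty vector and 64.7% for T286A against wild type. At a log2 change of 1 the shares were 94.9%, 90.6% and 93.3%. False calls made up 5.01%, 3.93% and 4.69% of calls. For both constructs together, 72.4% were recovered at 0.5 and 11.2% at 0.25. In simulations a list passed at an unadjusted camera p under 0.05 with the preset correlation, a looser rule than for the real lists. A list of 25 genes shifted by 0.3 in both constructs passed in 5 of 5 simulations against empty vector. It passed in 0 of 5 for T286A against wild type, where the planted difference was 0. A list shifted by 0.3 in T286A alone passed in 5 of 5 for that comparison, and an unshifted list in 0 of 5 for each comparison. Simulated genes varied independently, so these counts do not cover false calls of lists whose genes move together. Alternatives covered the replicate number as a block, the arrays in the fit, each array left out, dim genes left out, other treatments of probe sets, other eBayes settings, array weights, cyclic loess, centring on housekeeping genes and a fold threshold. Housekeeping centring made the median level of those genes equal across arrays, which need not bring their differences to 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.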

Results

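Gene expression in the B-cell line JVM13 was compared after induction of wild-type cyclin D1, of its T286A form or of an empty vector. Cyclin D1, encoded by CCND1, is the regulatory partner of CDK4 and CDK6. The T286A form lacks a phosphorylation site used for nuclear export and degradation of the protein. Array medians lay between 5.47 and 5.62 (log2). Wild-type replicate 2 stood apart. Its correlations with its own group were 0.994 to 0.995 across probe sets, against 0.997 between the other wild-type replicates. Its median distance from the probe set medians was 0.0942, against 0.0673 to 0.0802 in the other arrays, and its limma array weight was 0.513. The 3' minus 5' log2 differences of control probe sets ranged over the arrays from 0.077 to 0.11 for actin and from -0.158 to -0.117 for GAPDH.

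CCND1 was induced about equally in both constructs. Its brightest probe set averaged 5.12 ± 0.19 in empty vector (SD, n = 2), below the median of all genes. It was 5.95 ± 0.13 higher with wild-type cyclin D1, which is 61.6-fold (adjusted p = 5.22e-07), and 5.90 ± 0.13 higher with T286A, which is 59.8-fold (adjusted p = 5.54e-07). T286A minus wild type was -0.04 (95% interval -0.31 to 0.22, adjusted p = 0.902), so a difference in transcript level was not detected. The other CCND1 probe sets stayed between 3.85 and 4.69 in every array, constructs and controls alike. Averaged over all CCND1 probe sets the rise was therefore 1.52 with wild type and 1.44 with T286A, still called (adjusted p = 1.32e-05 and 0.000105). Their positions in the transcript were not examined.

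**Figure D1:**
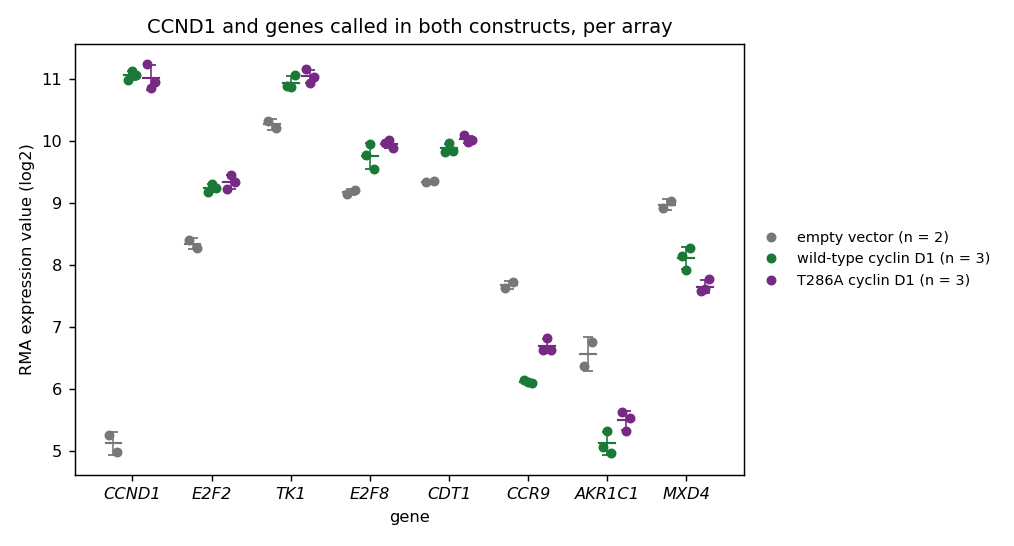
RMA expression (log2, vertical axis) of CCND1 and 7 genes called in both constructs; points are arrays, horizontal bars group means and error bars SD, for empty vector (n = 2), wild type (n = 3) and T286A (n = 3). CCND1 lies near 5.12 in controls and 11.04 in the construct arrays on average, E2F2, TK1, E2F8 and CDT1 are higher in all 6 construct arrays than in both controls, and CCR9, AKR1C1 and MXD4 are lower.

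Taking both constructs together against empty vector, genes of DNA replication and the G1/S transition rose. E2F2, a transcription factor of S-phase entry, rose by 0.95 ± 0.079 (6 against 2 arrays, adjusted p = 0.00401). TK1, a thymidine kinase, rose by 0.72 ± 0.086, the repressor E2F8 by 0.68 ± 0.10 and the replication licensing factor CDT1 by 0.61 ± 0.065. Of 34 measured E2F and G1/S genes, 21 were called higher and 0 lower; adjusted over the list alone, 33 were higher and 1, the cyclin E1 gene CCNE1, was lower. The list median was 0.38 (camera adjusted p = 2.07e-38, and adjusted p = 0.00173 with an estimated correlation). Of 29 G2/M and mitosis genes, all had positive differences and 8 were called higher, 27 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 3.59e-26). Examples were the kinase NEK2 at 0.44, the spindle protein NUSAP1 at 0.40 and cyclin A2, CCNA2, at 0.40. Among 18 genes of homologous recombination and fork repair, 4 were called higher and 12 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 6.29e-13). BRIP1 rose by 0.51, EXO1 by 0.47 and BLM by 0.40. The G2/M and repair lists held with an estimated correlation (adjusted p = 0.00173 and 0.00485). Other large rises were CYP4F2 (0.88), the caveolar protein CAV1 (0.81), ARHGAP5 (0.73), RMI2 (0.71), CDCA7 (0.67), MYBL1 (0.63) and ZNF367 (0.59). These are means over both constructs, and not every gene was called in each. MYBL1 and CAV1, for instance, were called with wild type and not with T286A. In the list of cyclin D partners and inhibitors, which was not called (camera adjusted p = 0.235), the phosphatase CDC25A rose by 0.35.

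NF-kappa-B targets fell in the same comparison. Of 21, 13 were called lower and 0 higher, and 17 were lower adjusted over the list alone. The median was -0.43 (camera adjusted p = 8.84e-23, and adjusted p = 0.00485 with an estimated correlation). The chemokine CCL22 fell by 0.68 ± 0.061, TNFAIP2 by 0.67 ± 0.079, the adhesion molecule ICAM1 by 0.62 ± 0.074 and the receptor CD40 by 0.60 ± 0.059. Immediate early genes were lower as a list (median -0.15, camera adjusted p = 1.53e-05, adjusted p = 0.0212 with an estimated correlation). Of 19, DUSP2 and EGR1 were called, and 8 were lower adjusted over the list alone. Also lower were the type I interferon list (median -0.11, adjusted p = 0.000357, and adjusted p = 0.0381 with an estimated correlation), with OAS3 called and 2 of 26 adjusted over the list alone, and MHC class II genes (median -0.16, adjusted p = 8.17e-05, and adjusted p = 0.0296 with an estimated correlation), with HLA-DQA1 called and 3 of 13 adjusted over the list alone. Taken separately, the immediate early and interferon medians were -0.31 and -0.15 with wild type, where both lists were called, and -0.05 and -0.01 with T286A, where neither was (camera adjusted p = 0.282 and 0.834). Likewise DUSP2, EGR1 and OAS3 were called lower with wild type and not with T286A. All of them were called higher with T286A than with wild type. The largest falls among named genes were those of the chemokine receptor CCR9 (-1.27 ± 0.072, adjusted p = 0.000473), AKR1C1 (-1.25), the proteoglycan VCAN (-1.17), LRRN3 (-1.09) and MXD4, a MAX dimerization partner and antagonist of MYC (-1.09 ± 0.10). S100A4, PLCB1, MMP7, IL12B, PRL, SERPINE2 and FRMD4A fell by 0.97 to 0.81. These means over both constructs cover unequal values. With wild type and T286A they were -1.79 and -0.55 for VCAN, -1.53 and -0.40 for S100A4, -1.49 and -0.45 for PLCB1, -1.47 and -0.29 for PRL and -1.41 and -0.29 for SERPINE2. For CCL22 they were -1.13 and -0.23, and for TNFAIP2 -0.94 and -0.41. With T286A limma called none of these 7 (adjusted p from 0.058 to 0.425), though the unadjusted p was under 0.05 for all but SERPINE2 (0.0537), and all 7 were called in T286A against wild type. LRRN3, too, was called with wild type and not with T286A. Within the B-cell identity list, FCER2 fell by 0.53.

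In total 255 of 18231 genes were called for both constructs together, 128 higher and 127 lower, and 2272 had an unadjusted p under 0.05. Of 28 lists, 4 were called higher and 11 lower, and 7 were called with an estimated correlation. The calls lost there were p53 targets (adjusted p = 0.068), ER stress (0.068), B-cell identity (0.1), MHC class I (0.12), homing and adhesion (0.0857), the BCL2 family (0.0809), cholesterol synthesis (0.1) and glycolysis and hypoxia (0.1). The gene count was far lower without either empty vector replicate, a fit that leaves a single control, and the cause was not tested. The count was 120 and 154 without wild-type replicates 1 and 3, and 88, 78 and 65 without T286A replicates 1, 2 and 3.

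Wild-type cyclin D1 against empty vector gave more calls, 317 genes, with 110 higher and 207 lower. At an unadjusted limma p under 0.05 the constructs were closer, with 2461 genes for wild type and 2205 for T286A. The actin nucleator FMN2 rose most after CCND1, by 3.65 ± 0.11 or 12.5-fold (3 against 2 arrays, adjusted p = 4e-06). LAMP5, a lysosome-associated membrane protein, rose by 1.82 ± 0.077, LGALS14 by 1.22, the chaperone CLGN by 1.13 and CAV1 by 1.00. NEBL, STK17B, CBLN2, E2F2, CYP4F2 and TENT5C rose by 0.98 to 0.88. The largest falls were VCAN (-1.79 ± 0.15), FMNL2 (-1.64), CCR9 (-1.56 ± 0.081), the calcium-binding protein S100A4 (-1.53 ± 0.072) and PLCB1 (-1.49). CCL20, FOS, PRL, GALM, AKR1C1, LRRN3 and SERPINE2 fell by 1.48 to 1.41.

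In wild-type cells 14 of 34 E2F and G1/S genes were called higher and 0 lower, or 32 higher adjusted over the list alone (median 0.36, camera adjusted p = 2.87e-29). The G2/M list rose with a median of 0.20 and 2 called genes, NUSAP1 and TTK (adjusted p = 8.89e-15), 17 adjusted over the list alone. The repair list rose with a median of 0.27 and 3 called genes, EXO1, BRIP1 and BLM (adjusted p = 5.56e-10), 11 adjusted over the list alone. NF-kappa-B targets fell with a median of -0.46 and 14 of 21 called lower, 16 adjusted over the list alone (camera adjusted p = 2.74e-21); CCL22 fell by 1.13 ± 0.068 and TNFAIP2 by 0.94 ± 0.089. Immediate early genes, which respond within minutes to growth signals, fell with a median of -0.31 and 5 of 19 called lower, 9 adjusted over the list alone (camera adjusted p = 4.33e-09). Among them FOS fell by 1.48 ± 0.17, EGR1 by 1.15 ± 0.090, DUSP2 by 0.98 and JUN by 0.64, and IER2 was also called. Interferon response genes were lower (median -0.15, camera adjusted p = 1.14e-06), with 3 of 26 called and 10 adjusted over the list alone. They were OAS3 (-0.98 ± 0.071), IFIT3 (-0.48) and MX2 (-0.45). Of 24 glycolysis and hypoxia genes 3 were called lower (median -0.14, camera adjusted p = 1.87e-05); adjusted over the list alone, 4 were lower and 1 higher. The aldolase ALDOC fell by 1.17 ± 0.086, PFKFB4 by 0.81 ± 0.086 and BNIP3 by 0.53. MHC class II fell (median -0.19, camera adjusted p = 2.01e-05) with HLA-DQA1, HLA-DRB1 and HLA-DQB1 called, 3 of 13 by either adjustment. Cholesterol synthesis genes were lower as a list (median -0.16, adjusted p = 4.63e-05), with 0 of 18 members called by limma, 2 adjusted over the list alone and 6 lower at an unadjusted p under 0.05. Its smallest p values belonged to LSS (-0.39) and MVK (-0.41).

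Those 9 lists were also called with an estimated correlation, the largest adjusted p being 0.0277, for cholesterol synthesis. The other 8 of the 17 called lists were not: p53 targets (adjusted p = 0.126 with an estimated correlation), ER stress (0.174), amino acid and integrated stress response (0.119), heat shock and proteasome (0.265), B-cell identity (0.115), MHC class I (0.103), homing and adhesion (0.131) and the BCL2 family (0.0518). Of other-lineage markers, the T-cell kinase LCK rose by 0.81 ± 0.10 and PRF1 fell by 0.65, while the T and NK list was not called (adjusted p = 0.788). VCAN, counted above, was the single called gene of the myeloid list (adjusted p = 0.21). The gene count was 43 and 22 without empty vector replicates 1 and 2, 153, 196 and 188 without wild-type replicates 1, 2 and 3, and 185, 191 and 172 without T286A replicates 1, 2 and 3. Centring on housekeeping genes changed the split to 155 higher and 152 lower, and the medians of the ER stress and B-cell identity lists then turned positive, at 0.00245 and 0.00756. The median of the housekeeping list itself moved from -0.00606 to 0.048 with that setting, so these changes may overstate a dependence on scaling.

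**Figure D2:**
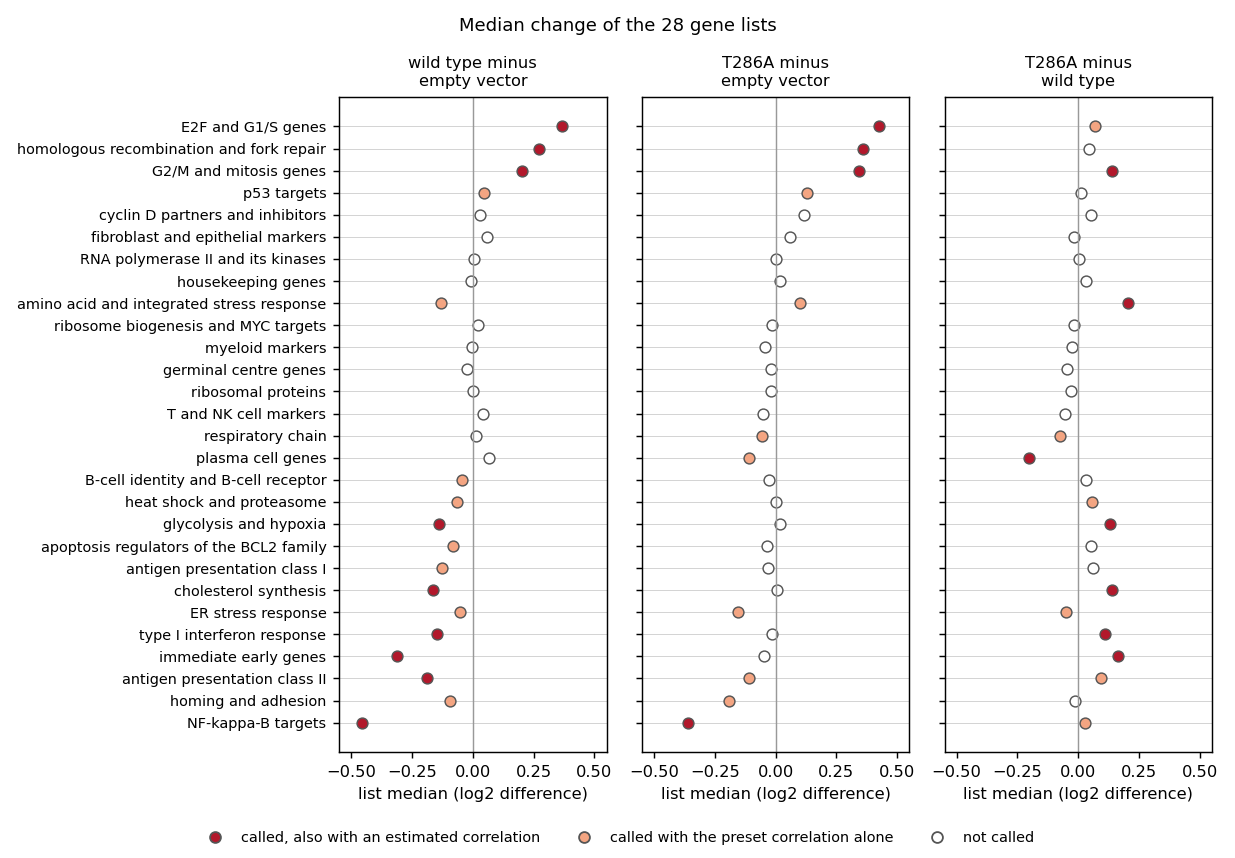
Median log2 difference of each of the 28 gene lists (horizontal axis) in 3 comparisons; filled points were called by camera, dark ones also with an estimated correlation, open points were not called. The E2F and G1/S list sits at 0.36 and 0.43 and the NF-kappa-B list at -0.46 and -0.36 in wild type and T286A, while the amino acid and stress response list lies at -0.13 and 0.10.

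T286A cyclin D1 against empty vector gave 97 called genes, 62 higher and 35 lower, and 5 of its 12 largest named rises were members of the E2F and G1/S list. E2F2 rose by 1.00 ± 0.088 (adjusted p = 0.00858), CDCA7 by 0.87, RMI2 by 0.78, E2F8 by 0.78 and TK1 by 0.78. ZNF367 rose by 0.73, E2F1 by 0.70 ± 0.070, CDT1 by 0.68 and DTL, a substrate receptor for the degradation of CDT1, by 0.64. CYP4F2 and the leukotriene receptor LTB4R rose by 0.88 and 0.76. The largest falls were MXD4 (-1.32 ± 0.11, adjusted p = 0.00858), TPRG1 (-1.14 ± 0.071, adjusted p = 0.00146), SLC35D2 (-1.10), AKR1C1 (-1.07) and CCR9 (-0.98). IL4I1, WNT5B, PNRC1, PHACTR1, TRAF1, FCRL2 and ATOSB fell by 0.81 to 0.65.

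The E2F and G1/S list had a median of 0.43 in T286A cells, with 14 of 34 members called higher and 32 adjusted over the list alone (camera adjusted p = 4.14e-38, and adjusted p = 0.00176 with an estimated correlation). G2/M genes had a median of 0.34, with 4 of 29 called and 27 adjusted over the list alone (adjusted p = 1.22e-30); NEK2 rose by 0.52 and HMMR by 0.45. The repair list had a median of 0.36, with BRIP1 and RAD51AP1 called and 11 of 18 higher adjusted over the list alone (adjusted p = 2.21e-12). NF-kappa-B targets had a median of -0.36, with 4 of 21 called lower and 17 adjusted over the list alone (camera adjusted p = 9.48e-18). TRAF1 fell by 0.67 ± 0.076, ICAM1 by 0.62, CCL3 by 0.60 and CD40 by 0.51. These 4 lists held with an estimated correlation, the largest adjusted p being 0.00879. The other 7 of the 11 called lists did not: p53 targets (adjusted p = 0.0626 with an estimated correlation), ER stress (0.0551), plasma cell genes (0.0551), homing and adhesion (0.117), MHC class II (0.129), respiratory chain (0.334) and amino acid and integrated stress response (0.302). By limma, 0 of 19 immediate early genes were called, 1 adjusted over the list alone; at an unadjusted p under 0.05, 2 were higher and 3 lower. Of 26 interferon response genes limma called 0 by either adjustment, and at an unadjusted p under 0.05, 2 were higher and 2 lower. FOS was at 0.09 (adjusted p = 0.901) and DUSP2 was at -0.36 (adjusted p = 0.109). The gene count was 1 and 2 without empty vector replicates 1 and 2, 3 without any of the T286A replicates, and 26 and 31 without wild-type replicates 1 and 3. Centring on housekeeping genes gave 31 higher and 41 lower.

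Genes called in both constructs included 36 higher and 30 lower. The rises covered CCND1, E2F2, TK1, RMI2, E2F8, CDT1 and MCM6, a subunit of the replicative helicase (0.49 and 0.58 in wild type and T286A), and also CYP4F2, the cytidine deaminase APOBEC3B and PMCH. The falls covered AKR1C1, CCR9, NRN1, MXD4, WNT5B, PHACTR1, FCRL2, ATOSB, ICAM1 and IL4I1. Independent lists of these sizes would share 0.37 and 0.40 genes, values that leave the shared controls out of account. In 100 simulations of unchanged groups against shared controls 0 genes were shared. With no changed gene almost none can be called, so this count is no benchmark for the overlap. Across genes, which are not independent replicates, the 2 sets of fold changes had a correlation of 0.532, against 0.6 in the simulations. Their covariance was 0.016 against a simulated 0.0104, a difference of 0.00564. A split of the 2 controls leaves 1 array per construct, an alternative added after the data were seen. With no shared array, unchanged groups have an expected covariance near 0, which was not simulated for this split. The covariance was then 0.00844 or 0.00743, by which control went to which construct, and CCND1 was the single shared call both ways. A single control also lowers the number of calls, to 22 or 43 with wild type and 1 or 2 with T286A, so part of the overlap may come from the shared arrays, and how much stays open. The count of 66 shared genes was 1 without either empty vector replicate, 2 without any of the T286A replicates, and 12, 36 and 18 without wild-type replicates 1, 2 and 3.

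**Figure D3:**
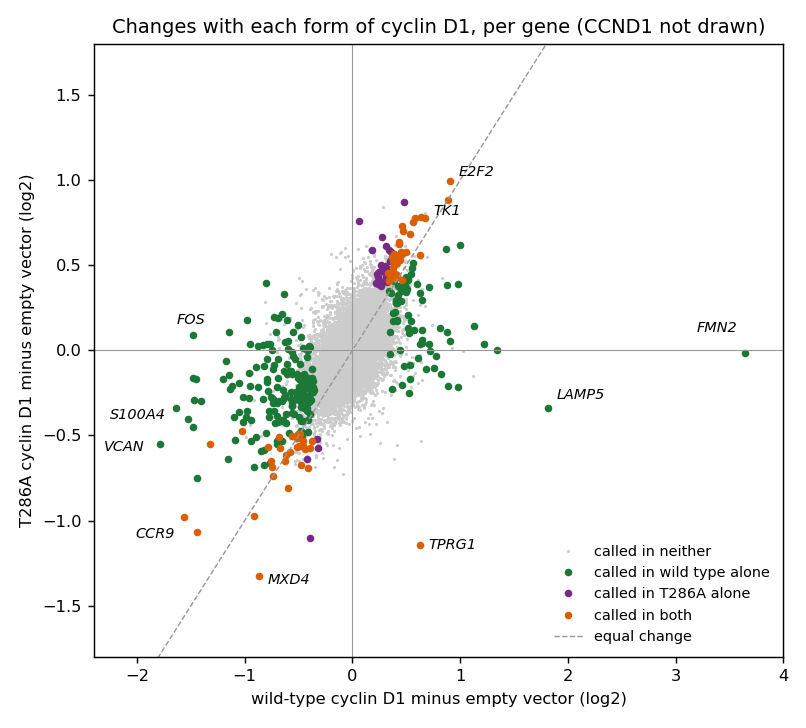
Log2 difference from empty vector with wild-type (horizontal) and T286A (vertical) cyclin D1 for 18202 genes, without CCND1 and Y-linked genes; colours mark genes called in 1, both or neither construct and the dashed line marks equal change. E2F2 lies near the line at 0.90 and 1.00, FMN2 at 3.65 and -0.01, and TPRG1 is called in opposite directions.

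The direct comparison of T286A with wild-type cyclin D1, 3 arrays against 3, called 180 genes, 109 higher and 71 lower in T286A cells. FMN2 was lower in T286A cells by -3.66 ± 0.098 (adjusted p = 3.11e-06) and LAMP5 by -2.15 ± 0.069. FMN2 averaged 4.38 ± 0.056 in empty vector, 8.02 ± 0.19 with wild type and 4.37 ± 0.080 with T286A (SD). TPRG1 was lower by -1.77 ± 0.064. NEBL, LGALS14, SAMSN1, TENT5C and RGS2 differed by -1.19 to -1.02, and CLGN, ELAPOR2, ELK3 and SPATA18 by -0.99 to -0.87. FOS was 1.57 ± 0.15 higher in T286A cells, FMNL2 1.30, GALM 1.29, MYOC 1.25, VCAN 1.24 and PFKFB4 1.2 ± 0.077. PRL, OAS3, S100A4, SERPINE2, ALDOC and VANGL2 were 1.18 to 1.10 higher.

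**Figure D4:**
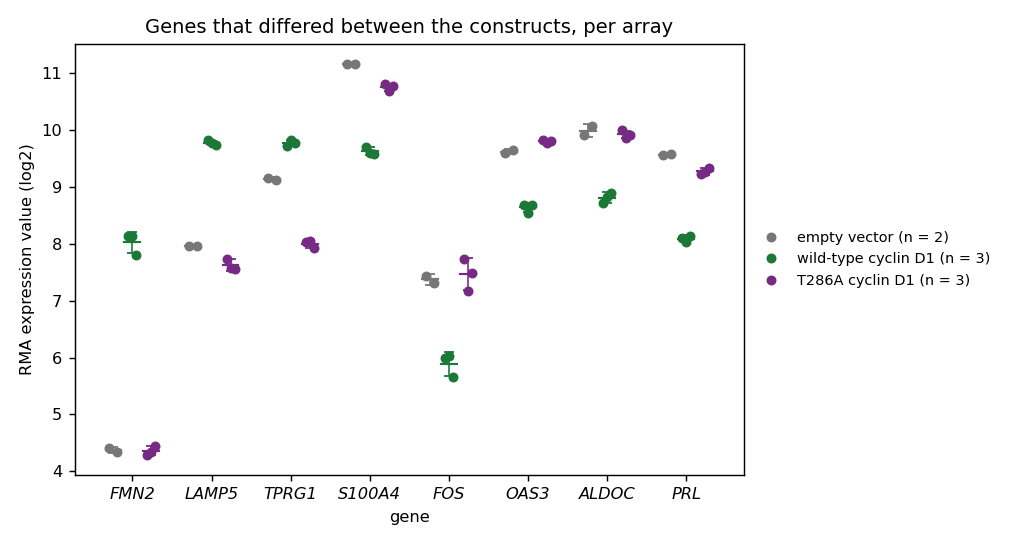
RMA expression (log2, vertical axis) of 8 genes that differed between T286A and wild-type cyclin D1; points are arrays, horizontal bars group means and error bars SD (empty vector n = 2, constructs n = 3). FMN2 averages 8.02 with wild type and 4.37 with T286A, while FOS averages 5.89 with wild type, 7.46 with T286A and 7.37 in empty vector.

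By list, immediate early genes were higher with T286A than with wild type (median 0.16, 5 of 19 called and 7 adjusted over the list alone, camera adjusted p = 6.93e-08), with EGR1 at 1.00 ± 0.081, JUN at 0.97, DUSP2 at 0.62 and IER2 also called. Glycolysis and hypoxia genes were higher (median 0.13, 4 of 24 called, adjusted p = 9.91e-08), including BNIP3L (0.49) and BNIP3 (0.48); adjusted over the list alone, 6 were higher and 1 lower. Interferon response genes were higher (median 0.11, 4 of 26 called, adjusted p = 8.79e-06), with OASL at 0.72, IFIT2 at 0.62 and IFIT3 at 0.56; adjusted over the list alone, 11 were higher and 1 lower. The amino acid and integrated stress response list was higher (median 0.21, 3 of 24 called and 9 adjusted over the list alone, adjusted p = 9.91e-08). Its called members were CTH of cysteine synthesis (0.72), PHGDH of serine synthesis (0.70) and the MTOR regulator DDIT4 (0.42). G2/M genes were higher with a median of 0.14 (0 of 29 called by limma, 5 adjusted over the list alone, 9 higher at an unadjusted p under 0.05, camera adjusted p = 9.91e-08), and cholesterol synthesis genes with a median of 0.14 (0 of 18 called, 3 adjusted over the list alone, 7 unadjusted, camera adjusted p = 1.28e-05). Plasma cell genes were lower with a median of -0.20, and JCHAIN, the joining chain of polymeric antibodies, differed by -0.64 ± 0.064 (1 of 14 called, 9 adjusted over the list alone, adjusted p = 6.93e-08). These 7 lists were also called with an estimated correlation, at adjusted p from 0.0153 to 0.0335.

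The other 6 of the 13 called lists were not called with an estimated correlation. Their adjusted p values there were 0.152 for E2F and G1/S genes, 0.249 for ER stress, 0.335 for heat shock and proteasome, 0.254 for NF-kappa-B targets, 0.114 for MHC class II and 0.179 for the respiratory chain. The E2F median was 0.07 and fell to -0.00519 with centring on housekeeping genes, and the heat shock and NF-kappa-B medians also turned negative there, at -0.02 and -0.05. Among NF-kappa-B targets CCL22 and TNFAIP2 were 0.91 and 0.53 higher with T286A. LCK of the T and NK list was lower by -0.68. Of the 250 genes called with wild type and not with T286A, 99 were called in the direct comparison, and of the 30 called with T286A and not with wild type, 3 were, LTB4R, SLC35D2 and USP37. Another 74 genes called in the direct comparison were called in neither construct against empty vector. Among the 66 shared genes, 3 also differed between the constructs, CCR9, MMP7 and TUBB2A. CCNE1, IER2, USP37 and TUBB2A were named after their values were seen. Centring on housekeeping genes turned the split of the direct comparison to 85 higher and 143 lower. The housekeeping list's own median moved from 0.0299 to -0.0442 with that setting, so the new split and signs may overstate a dependence on scaling. Its gene count was 92 and 96 without wild-type replicates 1 and 3, and 84, 70 and 72 without T286A replicates 1, 2 and 3.

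In none of the 4 comparisons was camera's adjusted p under the threshold for 9 lists, the smallest being 0.1 for cyclin D partners and inhibitors. The others were germinal centre genes (smallest adjusted p = 0.294), ribosomal proteins (0.224), ribosome biogenesis and MYC targets (0.553), RNA polymerase II and its kinases (0.542), T and NK cell markers (0.353), myeloid markers (0.158), fibroblast and epithelial markers (0.542) and housekeeping genes (0.282).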

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

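The tests on the CCND1 level, on wild-type replicate 2, on single control arrays and on the T286A runs of neighbouring genes were chosen after the results were seen. TPRG1 drew attention because it was called in opposite directions in the 2 constructs, at 0.63 with wild type and -1.14 with T286A, and the difference itself was -1.77 (limma adjusted p = 1.13e-05). Its levels were 9.14 ± 0.026 in empty vector, 9.77 ± 0.052 with wild type and 7.995 ± 0.071 with T286A (SD). The amino acid and integrated stress response list was also called in opposite directions, with medians of -0.13 and 0.10, and differed between the constructs by a median of 0.21. That difference was called in 16 of 16 alternatives with the preset correlation and had an adjusted p of 0.0335 with an estimated one. The 2 opposite calls are less firm, since with an estimated correlation the adjusted p was 0.119 for wild type and 0.302 for T286A, and the T286A rise was called in 8 of 16 alternatives with the preset correlation. Among 3634 probe sets without a single annotated gene, which the comparisons leave out, 19 were called for both constructs together against empty vector, 10 higher and 9 lower, and 302 had an unadjusted p under 0.05.

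The differences between T286A and wild type, 180 genes, were weighed against 4 technical accounts. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. As many genes were called in 1 split, the real one, with 180, and the highest of the others gave 0. A gain or loss of a chromosome region would put called genes into runs of neighbouring expressed genes that move together, but 0% of the 143 that could be placed lay in such runs of 25 genes, in a test that found all of a simulated block of 40 genes shifted by 0.4. The largest run had a median of 0.145 in size, close to the limit of 0.154, and against empty vector T286A cells had runs beyond the limit on chromosomes 1, 2 and 6. Of the 92 genes in those, 2 were among the 143, so a regional change is argued against as the source of most of the 143, while a smaller or weaker one stays open. A different amount of CCND1 transcript is argued against by the difference of -0.0437 (95% interval -0.308 to 0.22), and wild-type replicate 2 as the whole source by 103 of the 180 genes staying called without it. What stays open, and was not tested, is whether the genes differ because of the protein's form, its amount or a chance difference between cell populations. A difference between the groups in culture or array handling also stays open, since the labels give neither separate cultures nor scan dates. Which of these holds for FMN2, at 12.5-fold in wild-type cells and at the control level in T286A cells, was not tested.

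The rise of E2F genes and the fall of NF-kappa-B targets in both constructs share the same 2 controls. If 1 aberrant control array had caused them, leaving it out would bring a median near 0. The smallest median left was 0.317 in size, for E2F genes with wild type without empty vector replicate 2. A shift shared by genes of the same brightness is argued against by 10000 random lists matched on mean expression, of which 0 had a median as far from 0 as either list in any of the 3 comparisons against empty vector. The rise of E2F genes would go with the known role of cyclin D1 in freeing E2F factors, a hypothesis that was not tested here. No biological account of the fall of NF-kappa-B targets was tested. A difference between the control population and both construct populations that is unrelated to cyclin D1 was not tested.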

How the results depend on the processing

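All settings below were planned before the data were examined, except separate control arrays for the 2 constructs, which were added afterwards. With a replicate block the counts of called genes were 7 for both constructs together, 71 for wild type, 3 for T286A, 86 for T286A against wild type and 2 shared. Pairing of samples by replicate number was not clear. Deviations of same-numbered samples had correlations of -0.0909 to 0.119, and not every sample correlated best with its own number. Deviations within a group of 2 or 3 arrays depend on each other, so this check cannot exclude a batch shared by replicate number. The block uses up 2 of 5 residual degrees of freedom. With only the compared groups in the fit, the counts were 68 for wild type, 4 for T286A and 1 shared. Leaving out 1 array at a time gave 3 to 199 genes for both constructs together, 22 to 196 for wild type, 1 to 87 for T286A, 70 to 128 for T286A against wild type and 1 to 36 shared. Each of these fits has fewer arrays, and a single control is assumed to vary like the other groups. The losses differed between arrays, and their cause was not tested. In the same order of 5 counts, leaving out genes under the median intensity gave 624, 629, 527, 381 and 261, and eBayes with trend and robust gave 738, 747, 626, 602 and 322. A fold of at least 1.5 gave 63, 146, 34, 109 and 15. The mean of a gene's probe sets gave 190 for T286A and 107 shared, testing every probe set gave 62 and 39, and array weights gave 317 and 121, with 436 for both constructs together. The cause of the larger counts was not tested, except that fewer genes were tested with the intensity filter. Cyclic loess and centring on housekeeping genes kept the counts within 1.5 times, and the largest shift of the median of all genes was -0.0738, for T286A against wild type. In that comparison the housekeeping list's own median was 0.0299 before the centring and -0.0442 after it. With separate control arrays, 1 per construct, 1 gene was shared whether wild type was set against control 1 or control 2. Each construct then had a single control. Camera with an estimated correlation called 7, 9, 4 and 7 lists. The correlation alone does not account for the lost calls, since that setting also has fewer degrees of freedom. For both constructs together, the BCL2 family had an estimated correlation of -0.0121, under the preset 0.01. Its camera adjusted p still rose from 0.0118 to 0.0809.

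The CCND1 difference between T286A and wild type ranged from -0.158 to 0.0373 with 1 array left out. It turned positive without T286A replicate 2, and the cause was not tested. Its rise against empty vector stayed called in every alternative, but was 1.48 for both constructs together with the mean of its probe sets. With the mean of a gene's probe sets, CDK12 in T286A against wild type became 0.0301 and EDEM1 in wild type became 0.0296; neither was called. Of 195 called results for genes in the comparisons that the rule chose them for, CCND1 apart, 0 reversed in any alternative; 61 and 55 stayed called without empty vector replicates 1 and 2, 67 with the block, 193 with array weights and 195 with trend and robust. These results were chosen because they were called, so few could reverse, and the 0 reversals say little about robustness. Centring on spiked controls was not run, because the table used here held only human control probe sets. Without detection calls, dim genes have no measured floor.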

Other observations

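The tests here were chosen after the results were seen, except the search for runs of neighbouring genes, whose split by histone genes was added afterwards. Replication-dependent histone genes, which are made in S phase, were in none of the fixed lists. Of 60 such genes, 51 had positive differences from empty vector with wild-type cyclin D1 and 48 with T286A. Limma called 5 higher with wild type and 0 with T286A, with 0 lower in either; at an unadjusted p under 0.05, 21 and 23 were higher and 0 lower. The medians were 0.24 and 0.22, and 0.36 and 0.30 among the 24 genes above the median intensity. Camera's p was 1.29e-11 and 2.5e-10, and 0.00672 and 0.00886 with an estimated correlation. For both constructs together 4 were called higher and 0 lower, namely H2AC8 (0.48), H2BC11 (0.47), H2BC8 (0.43) and H2BC9 (0.54). Between the constructs the histone list had a median of -0.02 and was not called. Histone genes resemble each other closely, so single members are uncertain, and the rise was found and tested on the same data. Whether it goes together with that of the G1/S genes was not tested.

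In both constructs the largest run of neighbouring genes lay on chromosome 6, at 0.245 in size with wild type and 0.186 with T286A. With wild type, 12 runs of 25 neighbouring expressed genes moved beyond the 95th percentile of shuffled gene orders, all on chromosome 6. They covered 46 genes, 22 of them histone genes, and the median without the histones was 0.01. With T286A, 6 such runs lay on chromosome 6, covering 34 genes with 22 histones, and the median without them was -0.04. A further 4 runs on chromosome 1 and 6 on chromosome 2 had medians of -0.15 and held 0 histone genes. The same genes had medians of -0.0716 and -0.105 with wild type, and of -0.0644 and -0.0447 for T286A against wild type, where no run passed the limit.

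G1/S genes were compared with G2/M genes because the medians of the 2 lists differed, so the test below uses the values that prompted it. The mean of the E2F and G1/S list minus that of the G2/M list was -0.39 and -0.41 in the empty vector arrays, -0.26 to -0.22 with wild type and -0.32 to -0.28 with T286A. For the 6 construct arrays together, the difference of 0.127 had a two-sided exact permutation p of 0.0357, the smallest that 28 splits of 8 arrays can give. It was 0.157 with wild type and 0.098 with T286A, and the arrays of the 2 constructs did not overlap. For each of these and for the 0.0589 between the constructs p was 0.1, the smallest these group sizes allow, so whether the constructs differ is open. No cell-cycle distribution was analysed here, so a change in the share of cells per phase and a change per cell cannot be separated by these values.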
